A study of Mus musculus with 6 samples.

How the data were processed

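ChIP-seq was performed on retinoic acid-differentiated mouse embryonic stem cells with doxycycline-inducible Oct4. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sheared by sonication, and antibodies against Oct4, Spt16 and Jmjd1c were used. The 6 libraries were grouped by antibody and time as their titles state, and each group held 1 library. Per the submitters' processing notes, reads were handled with CASAVA 1.4 and Bowtie (version not given in the sources used here) on the mm9 build. The region caller is not given in the sources used here.

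Regions were called by the authors in each 10 h ChIP library against the 10 h input library, per the file headers, and kept at a log2 ratio of at least 1 and a Q value score of at least 13 on a -10 log10 scale, about 0.05. The deposited table for each antibody gives, for the best window of each region, whole-number read counts per strand for ChIP and input. Counts were summed over strands. The authors' log2 value is the log2 ratio of ChIP reads, scaled to the input total, to input reads, with 1 added to each, which the deposited counts reproduced within 0.0001 for each region. The authors' score is -10 log10 of a binomial p-value, which the deposited counts and library totals gave back within 0.001 for each region; that the Q value column uses the same scale was inferred from the threshold. Score sizes were not compared between lists, but scores were correlated between lists at shared regions, and the lowest Oct4 score served as the minimum for thinned libraries. Per the file headers, 10 regions found in uninduced cells were removed from the Oct4 list. Rank numbers ran to 286, 1302 and 52, so 21, 49 and 28 rank numbers were absent from the Oct4, Spt16 and Jmjd1c lists, and the regions behind them were not analysed here. The deposited gene tables name genes around each region, with a distance in bp from the middle of the region to the gene start. No gene was listed for 38 Oct4, 133 Spt16 and 5 Jmjd1c regions. Coordinates are given as deposited. No column of values was left without a match to a library.

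Depth was read from the library totals in the file headers (15.5 M, 36.7 M, 26.7 M and 14.6 M reads for Oct4, Spt16, Jmjd1c and input). With 0 input reads, a fold was taken against a floor of 3 input reads, 0.206 RPM (reads scaled to the library total), and given as a lower bound. With 1 or more, the ratio of RPM was given with an exact binomial counting interval. ChIP reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Shares have 95% Clopper-Pearson intervals. A fixed input library served all 3 lists, so errors in it are shared by them.

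Lists were compared by overlap of at least 1 bp. Counts from bedtools 2.31.1 equaled those of the repositioning code for each pair. Significance came from 10000 repositionings of the smaller list, each region at a uniform position on its own chromosome, whose length was taken as the largest coordinate seen in any list. Correlations and differences in medians used 100000 resamples, two-sided. Gene symbols were matched, through current symbols and synonyms, to 21900 protein-coding genes of a RefSeq table on GRCm38.p6, used for names only. Of the distinct gene identifiers, 432 of 633 (68.2%) matched for Oct4, 2069 of 3203 (64.6%) for Spt16 and 41 of 65 (63.1%) for Jmjd1c, and the others, among them noncoding genes and pseudogenes, were left out of gene tests. The 7 preset lists covered pluripotency, retinoic acid response, germ layer regulators, chromatin regulators, cell cycle and growth, housekeeping and stress, and fibroblast or extraembryonic markers. Each was compared with all other genes by a two-sided Fisher's exact test. Fisher tests treat genes or regions as independent units, which neighbors are not. Adjustment was by Benjamini-Hochberg within each family of tests. Lists, designs and the first set of alternatives were fixed before the data were examined. Named regions were the 10 with the highest authors' score in each list, the members of preset lists with a region, up to 10 per list and table by score, and up to 10 regions in all 3 lists; others are marked where named.

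The alternatives were the higher-scoring part of each list, other overlap rules, other repositioning, merged regions, autosomes only, other gene distances, the Q score and, added after seeing the data, thinning of ChIP reads to the Oct4 total in 100 draws, ChIP reads alone, distances from region edges, other gene backgrounds and removal of regions at histone and U RNA genes. Code was tested on simulated data. For lists of the Oct4 and Spt16 sizes, 0 of 100 random pairs and 100 of 100 pairs with 20 planted shared regions were called. For a list of 45 genes among 21900, 3 of 100 random lists and 100 of 100 with 15 planted members were called. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A search for the octamer sequence in the regions was not run, because a genome sequence was not used here.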

Results

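The series profiled DNA occupancy by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic stem cells of C57BL/6 background carrying a doxycycline-inducible Oct4 gene. Oct4, the product of Pou5f1, is the POU transcription factor that maintains pluripotency. The cells were first differentiated with retinoic acid, which shuts off the endogenous pluripotency program, and then received PBS or doxycycline, so that occupancy could be read at newly made Oct4. Besides Oct4, the antibodies were against Spt16, a subunit of the histone chaperone FACT, and Jmjd1c, a Jumonji-family protein related to histone H3 lysine 9 demethylases. The 6 libraries comprised Oct4 at 0 h and 10 h, Spt16 at 10 h, Jmjd1c at 10 h, and input chromatin at 0 h and 10 h, with 1 library for each. The region tables compared each 10 h ChIP library with the 10 h input, and the 0 h libraries were not analysed here. Library totals were 15543450 reads for Oct4, 36669596 for Spt16, 26736842 for Jmjd1c and 14592994 for the input. Without replicates, every interval below covers counting error only, and every p-value describes regions or genes within these libraries, not variation between cultures.

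Which sites did each antibody mark 10 h after induction? The highest-scoring region left in each of the 3 lists lay inside Abca4, on chromosome 3 at 121848236 to 121848751 (mm9) in the Oct4 list. It had rank 1 for Oct4 and Spt16 but rank 6 for Jmjd1c, where the rank numbers before it were absent. It held 84 Oct4 reads, 217 Spt16 reads and 46 Jmjd1c reads in the best window, against 0 input reads, so enrichment over the input floor of 3 reads was at least 26.3-fold, at least 28.8-fold and at least 8.37-fold. The DNA upstream of Pou5f1 itself was the third region of the Oct4 list by rank and was listed for all 3 proteins. It lay on chromosome 17 at 35640795 to 35641195, with its middle 1986 bp from the deposited gene start (ENSMUSG00000024406). There, Oct4 gave 40 reads, Spt16 170 and Jmjd1c 24 against 0 input reads, or at least 12.5-fold, at least 22.6-fold and at least 4.37-fold over the floor. The Oct4 list held 265 regions covering 63.8 kb, the Spt16 list 1253 regions covering 378.8 kb and the Jmjd1c list 24 regions covering 6.02 kb. Median ChIP reads per region were 18, 37 and 32.5, which came to 1.16, 1.01 and 1.22 RPM (reads scaled to the library total). No input read fell in 191 Oct4 regions (72.1%, 95% Clopper-Pearson interval 66.3 to 77.4), 852 Spt16 regions (68.0%, 65.3 to 70.6) and 15 Jmjd1c regions (62.5%, 40.6 to 81.2). Every Oct4 region with under 19 reads was without an input read. The Oct4 share therefore depends on the calling threshold and read number, not on the input alone. The list sizes compare libraries of unequal depth. With Spt16 reads thinned at random to the Oct4 total, 594 ± 12.8 Spt16 regions (SD over 100 draws) still passed the Oct4 list's lowest score, and 14.3 ± 1.85 Jmjd1c regions did.

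**Figure D1:**
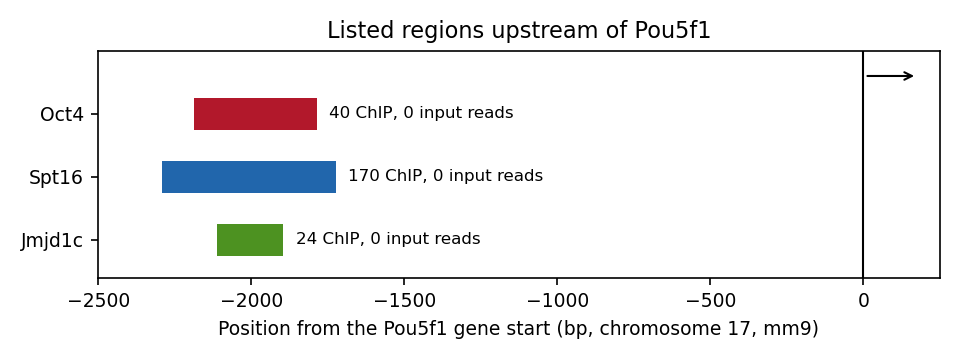
Listed regions upstream of Pou5f1 on chromosome 17, drawn in bp from the gene start (vertical line, with an arrow for the direction of transcription); each bar is the region deposited for that antibody, with its ChIP and input reads in the best window. The Oct4 region runs from 2186 to 1786 bp upstream, and lies within the Spt16 region, which runs from 2293 to 1724 bp.

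Other top Oct4 regions by score lay near Slain2 on chromosome 5 (73293611 to 73293867; 40 reads against 0 input reads), near a SNORA17 gene on chromosome 17 (48755584 to 48755930; 50 reads against 3), near a U7 gene and 39519 bp from Col14a1 on chromosome 15 (55099612 to 55099959; 35 against 0), and 47434 bp from Prr5 on the same chromosome. The remaining members of the top 10 lay 12298 bp from a U1 gene on chromosome 14, inside Rnf220, near Samd13 and inside Slc35f4, with 32 to 38 reads each. In the Spt16 list, the Abca4 region was followed by SNORA17, Pou5f1 and Rif1, whose product acts in telomere and replication-timing control and is abundant in pluripotent cells. The Rif1 region (chromosome 2, 51927524 to 51928069) had its middle 560 bp from the gene start and held 170 Spt16 reads, 28 Oct4 reads and 25 Jmjd1c reads, with 0 input reads for each. The other Spt16 top regions included those 12300 bp from the chromosome 14 U1 gene (144 reads), inside Sema5b (139) and 5655 bp from the chromosome 15 U7 gene (124). The rest were inside Slc35f4 (122), inside Cnpy1 and 44356 bp from En2 (132), and inside Rnf220 (127). Each of the 10 highest Spt16 regions was also in the Oct4 list.

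Did Spt16 lie where Oct4 lay? Of the 265 Oct4 regions, 168 overlapped a Spt16 region by at least 1 bp (63.4%, 95% Clopper-Pearson interval 57.3 to 69.2), among them Pou5f1, Nanog, Rif1, Klf2, Lefty1, Fbxo15 and Rest. Shared regions included all of the 20 highest-scoring Oct4 regions, 89 of the 100 highest and 42 of the 100 lowest. In the other direction, 13.4% of Spt16 regions (11.6 to 15.4) overlapped an Oct4 region, with 18 of the 20 highest and 2 of the 100 lowest. With Spt16 reads thinned to the Oct4 total, the share was 22.7% (135 of 594). At Nanog, the homeobox gene of the core pluripotency network, the Oct4 region (chromosome 6, 122657330 to 122657491) had its middle 96 bp from the gene start and held 24 reads against 2 input reads, an 11.3-fold excess (95% counting interval 2.8 to 98.4). The Spt16 region there held 51 against 2, a 10.1-fold excess (2.67 to 86.1). Repositioning the Oct4 regions at random along their chromosomes gave a mean of 0.0731 shared regions and never more than 3, for a two-sided permutation p of 0.0002, the smallest that 10000 repositionings can give (Benjamini-Hochberg adjusted p = 0.0002 over 3 pairs). The lists shared the same input library, so its errors are common to them.

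At the 168 shared regions, Oct4 and Spt16 scores rose together. The authors' binomial scores correlated across regions with Spearman's rho 0.56 and Pearson's r 0.75 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give; adjusted p = 3e-05 over 3 pairs), and without the 2 regions farthest from the median r was 0.71. Regions are not independent replicates. Shuffling the Spt16 reads among regions while keeping their input reads gave a mean rho of -0.026 (95% of shuffles from -0.17 to 0.13). The shuffle covers the shared input only. Local coverage common to both ChIP libraries would also give a positive rho and was not tested. The median ratio of Spt16 RPM to Oct4 RPM was 1.14 (bootstrap 95% interval 1.08 to 1.21; range 0.52 to 2.8). Spt16 was higher beyond counting error at 21 regions and lower at 2, where counting error alone would give 4.2 each way. That expectation ignores how the regions were chosen. Each had to be called in both lists, with at least 15 Oct4 and 26 Spt16 reads, which limits low ratios at regions with few Oct4 reads. The 21 against 2 therefore does not test which protein was higher. Oct4 regions with a Spt16 region had a median of 20 Oct4 reads, against 16 at the 97 without. Their median authors' score was higher by 7.21 (51.8 against 44.5; permutation p = 1e-05, adjusted p = 2e-05 over 6 tests). Spt16 regions with an Oct4 region had a median of 55 Spt16 reads, against 35 at the 1085 without, and a median score higher by 31.9 (permutation adjusted p = 2e-05).

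**Figure D2:**
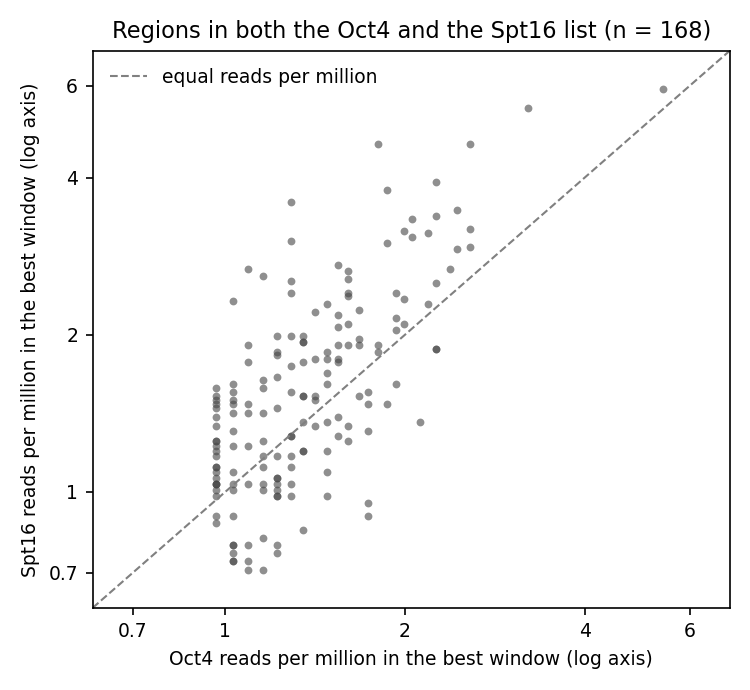
RPM in the best window of the Oct4 library (x axis, log scale) and of the Spt16 library (y axis, log scale) at the 168 regions in both lists, 1 point per region, with the dashed line marking equal values. The median Spt16 to Oct4 ratio was 1.14, and the Abca4 region is the point farthest to the right.

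Jmjd1c regions were few, and overlapped Oct4 and Spt16 regions more often than random positions did. Of the 24, 13 overlapped an Oct4 region (54.2%, 32.8 to 74.4), 14 a Spt16 region (58.3%, 36.6 to 77.9), and 11 both. Besides Abca4, Pou5f1 and Rif1, the regions in all 3 lists included those near the chromosome 14 U1 gene (41 Jmjd1c reads) and Slain2 (35), those inside Iqgap1 (33), Slc35f4 (30) and Ncam2 (24), and a pair on chromosomes 8 and 9 beside which no gene was listed (36 and 30). Random repositioning gave a mean of 0.0012 regions shared with Oct4 and 0.0067 with Spt16 (permutation p = 0.0002 for each, the smallest possible; adjusted p = 0.0002). Without the widest 5% of each list, 22.7% (5) still overlapped a Spt16 region. Without regions in all 3 lists, which lowers the shares by construction, 23.1% (3) overlapped a Spt16 region and 15.4% (2) an Oct4 region. The 14 Jmjd1c-marked Spt16 regions had a median of 103 Spt16 reads, against 37 at the other 1239 (score difference 101.8, permutation adjusted p = 2e-05), and the 13 Jmjd1c-marked Oct4 regions a median of 27 Oct4 reads, against 18 at the other 252 (score difference 24.7, permutation adjusted p = 4.5e-05). Jmjd1c scores correlated with Oct4 scores over the 13 shared regions (rho 0.72, permutation p = 0.0073, adjusted p = 0.011; r = 0.76, permutation p = 0.0039). Shuffling the Jmjd1c reads among these regions while keeping their input reads gave a mean rho of 0.10 (95% of shuffles from -0.42 to 0.66). Without the 2 regions farthest from the median neither passed the threshold (permutation tests over 11 regions). The linear relation rested on those 2 (r = 0.40, permutation p = 0.23), while rho was 0.58 (permutation adjusted p = 0.098), a loss that fewer regions alone can bring. With ChIP reads in place of scores, r passed (0.70, permutation adjusted p = 0.012) and rho did not (0.57, permutation adjusted p = 0.064). Jmjd1c regions on Spt16 regions scored higher than the others by 10.0 (permutation adjusted p = 0.028), but not in ChIP reads alone, where their median differed by -2.5 (permutation adjusted p = 0.65). With Spt16 scores no correlation passed the threshold (rho 0.37 and r = 0.46 over 14 regions, permutation adjusted p = 0.19 and 0.095; without the 2 farthest, r = -0.017).

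Were pluripotency genes among the neighbors? Of 45 pluripotency genes listed before the data were examined, 12 had an Oct4 region within 50 kb and 30 had a Spt16 region. With Spt16 reads thinned to the Oct4 total, the median draw had 19 (odds ratio 19.9). The 12 with an Oct4 region were Pou5f1, Nanog, Klf2, Lefty1, Lefty2, Dppa3, Gdf3, Rif1, Jarid2, Phc1, Rest and Fbxo15, and each of them also had a Spt16 region within 50 kb, as a gene-level count that does not require the same region. Dppa3, a germline and naive-pluripotency marker, had an Oct4 region 1781 bp from its start (29 reads against 2), and Lefty1, a Nodal antagonist, had one 1095 bp away (34 reads against 1). Among the 10 pluripotency genes with the highest Spt16 scores were Sox2, the usual partner of Oct4 on DNA, with a Spt16 region 4050 bp away (chromosome 3, 34552763 to 34553189; 89 reads against 2, a 17.7-fold excess, 4.76 to 148.5), and Id3, an inhibitor of differentiation, with one 3397 bp away (70 reads against 1). Neither had an Oct4 region within 50 kb. In all, 18 of the 30 had none, among them, named here after their values were seen, Nodal, Utf1, Mycn, Prdm14, Sall4, Tdgf1 and Zfp42. Absence from the Oct4 list does not show absence of Oct4. The Oct4 library had fewer reads than the Spt16 library, and 10 regions found in uninduced cells were removed from its list. The Oct4 share was 26.7% (14.6 to 41.9), against 1.42% of 21900 protein-coding genes (odds ratio 26.3, two-sided Fisher's exact test, adjusted p = 1.04e-11 over 21 tests of 7 lists and 3 tables), and the Spt16 share was 66.7% (51.0 to 80.0), against 7.15% (odds ratio 26.5, adjusted p = 8.15e-23). Against the genes of the other preset lists alone, the odds ratios were 11.2 and 8.97. For Jmjd1c, 2 genes, Pou5f1 and Rif1, were marked (odds ratio 37.6, Fisher's exact test, adjusted p = 0.0068). That call was lost when only the higher-scoring part of the list was kept, which held 0 of the 45 genes. It also did not pass against the genes of the other preset lists alone (Fisher's exact test, adjusted p = 0.17).

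Of the other preset lists, 3 passed the threshold for Spt16: chromatin regulators, housekeeping genes and cell cycle genes. Spt16 regions lay beside 12 of 42 chromatin regulators (28.6%, 15.7 to 44.6; odds ratio 5.23, Fisher's exact test, adjusted p = 0.00018), including Jarid2, the Polycomb-associated Jumonji protein (116 reads against 1), Tet2, a 5-methylcytosine oxidase (71 against 1), Kdm3b, a relative of Jmjd1c (75 against 4), and Jmjd1c itself (56 against 3). Beside 8 of 22 housekeeping and stress genes (36.4%, 17.2 to 59.3; odds ratio 7.46, Fisher's exact test, adjusted p = 0.00045) they included Gapdh (117 against 5, at its highest-scoring region, 48790 bp away), Hspa8 (43 against 1), Rps18 (34 against 0), Hsp90ab1 (37 against 1) and Eef1a1 (31 against 0). Gapdh had 3 Spt16 regions within 50 kb, the nearest 1011 bp from its start. Cell cycle and growth genes had 6 of 20 (30.0%, 11.9 to 54.3; odds ratio 5.59, Fisher's exact test, adjusted p = 0.0075), which were Mycn (50 against 0), Trp53 (78 against 4), Ccnd3, Myc (25586 bp away), Cdk1 and Cdkn1a (47089 bp away). Mycn, and Jarid2 among the chromatin regulators, were also on the pluripotency list, so their regions count in both. In the higher-scoring part of the Spt16 list the cell cycle count was 3 of 20 and no longer passed (odds ratio 4.48, Fisher's exact test, adjusted p = 0.14; 0.0021 to 1 over its alternatives). Against the genes of the other preset lists alone, none of these 3 lists passed (odds ratios 0.979 for chromatin, 1.47 for housekeeping and 1.06 for cell cycle genes; Fisher's exact test, adjusted p = 1 for each), while retinoic acid genes (0.147), germ layer regulators (0.214) and fibroblast or extraembryonic markers (0) had fewer Spt16 regions (adjusted p = 0.015, 0.040 and 0.035). The comparison genes there included the pluripotency list, of which 66.7% had a Spt16 region. Against all genes, the odds ratios of those last lists were 0.928, 1.34 and 0, and none passed the threshold by Fisher's exact test. Oct4 regions lay beside 3 chromatin regulators (Jarid2, Tet2 and Wdr5; odds ratio 5.40, Fisher's exact test, adjusted p = 0.064), 1 housekeeping gene (Gapdh, 48727 bp away; adjusted p = 0.71) and 0 cell cycle genes (adjusted p = 1), none of which passed the threshold. Whether Oct4 and Spt16 differed on any of these lists was not tested.

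Retinoic acid response genes and germ layer regulators did not differ from the background by the test. Rarg, a retinoic acid receptor, had an Oct4 region inside the gene (chromosome 15, 102073625 to 102073924; 23 reads against 2) that overlapped a Spt16 region, and Rxra, its heterodimer partner, had a Spt16 region (32 against 0), for 1 of 30 and 2 of 30 genes (Fisher's exact test, adjusted p = 0.77 and 1). Sox7, an endoderm regulator, had a region in both the Oct4 list (21 reads against 0) and the Spt16 list (50 against 0), and Sox3 (37 against 0) and Pax6 (26 against 0), which act in neural progenitors, had Spt16 regions, for 1 of 32 and 3 of 32 (Fisher's exact test, adjusted p = 0.77 and 0.95). No gene of the 15 fibroblast or extraembryonic markers had a region within 50 kb in any table (Fisher's exact test, adjusted p = 1 for each), which still allows a share of up to 21.8% by the upper exact bound. Jmjd1c had 0 genes of every list except pluripotency.

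**Figure D3:**
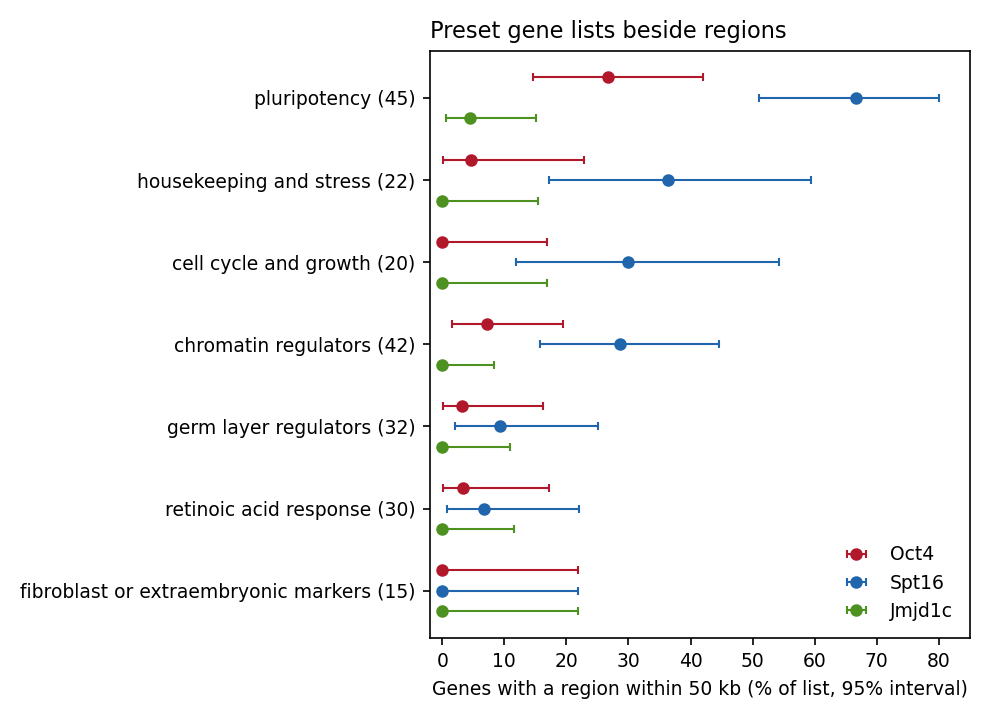
Percent of each preset gene list (list size in parentheses) with a region within 50 kb in the Oct4, Spt16 and Jmjd1c gene tables; points are the shares and bars the 95% Clopper-Pearson intervals over genes. Pluripotency stands highest for Spt16 (66.7%) and for Oct4 (26.7%), against backgrounds of 7.15% and 1.42% of protein-coding genes.

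At the level of all neighboring genes, the Oct4 and Spt16 tables named 312 protein-coding genes in common, where independent lists of 430 and 2047 genes would share 40.2 (odds ratio 30.1, Fisher's exact test, adjusted p = 3.24e-227 over 3 pairs). Oct4 and Jmjd1c shared 25 genes against 0.785 (odds ratio 88.3, Fisher's exact test, adjusted p = 4.86e-33), and Spt16 and Jmjd1c shared 24 against 3.74 (odds ratio 14.7, adjusted p = 2.49e-15). With only the nearest gene of each region, the odds ratios were higher, at 78.4, 279.9 and 85.9. Genes beside the same region enter together, so these p-values are too small. A region in both lists names the same genes in both tables. The gene overlap therefore follows in part from the region overlap and is not separate evidence for it.

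How close to gene starts did the regions lie? Oct4 regions were mostly distal, like the ones near Slain2 (11803 bp) and Samd13 (8080 bp), and 16 of 265 (6.04%, 3.49 to 9.62) lay within 1 kb of a gene start, those at Nanog, Rif1 and Fbxo15 among them. Spt16 regions lay within 1 kb in 160 of 1253 cases (12.8%, 11 to 14.7), a difference of 6.73 percentage points (Fisher's exact test, p = 0.0014, adjusted p = 0.0085 over 6 tests). Of the 160, 56 lay at histone genes and U-type small nuclear RNA genes. Without them, which lowers the Spt16 share by construction, that share was 8.69% and the difference 2.65 points (Fisher's exact test, p = 0.17, adjusted p = 1, an alternative chosen after seeing the data). In the higher-scoring parts of the lists the difference was 6.58 points and no longer passed (Fisher's exact test, adjusted p = 0.0996; 0.020 to 1 over its alternatives). Within 10 kb, the shares were 35.8% for Oct4 and 41.7% for Spt16 (Fisher's exact test, adjusted p = 0.26). For Jmjd1c, 1 region, at Rif1, lay within 1 kb and 9 within 10 kb. Over the 227 Oct4, 1120 Spt16 and 19 Jmjd1c regions with a listed gene, median distances to the nearest gene start were 14.1 kb, 11.2 kb and 10.1 kb. Of all regions in these lists, 42.6%, 49.6% and 37.5% overlapped a gene.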

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

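The tests in this part were chosen after the results were seen, except that of distance to gene starts.

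The share of regions within 1 kb of a gene start differed between Spt16 (12.8%) and Oct4 (6.04%) by 6.73 points, by Fisher's exact test of the difference itself (adjusted p = 0.0085). It did not pass in the higher-scoring parts of the lists (6.58 points, Fisher's exact test, adjusted p = 0.0996; 0.020 to 1 over its alternatives), nor without regions at histone and U RNA genes (2.65 points, adjusted p = 1), whose removal lowers it by construction.

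Chromosome 8 held 34 of the 265 Oct4 regions (12.8%, 9.05 to 17.5), among them the one near Klf2, against 80 of the 1253 Spt16 regions (6.38%, 5.09 to 7.88), a difference that passed the threshold over 21 chromosomes (Fisher's exact test, p = 0.00073, adjusted p = 0.015). Many were weak: 18.9% of the 106 Oct4 regions with 15 or 16 reads lay on chromosome 8, against 8.81% of the other 159 (Fisher's exact test, p = 0.023, not corrected). The excess was thus larger among regions with the fewest reads the threshold admits, which does not show why they lay on chromosome 8. An extra copy of chromosome 8 in part or all of the cells stays open: input reads per Spt16 region there were 1.18 times those on other autosomes (0.872 to 1.58), but they were counted only at listed regions, which were chosen for low input, so the ratio does not measure copy number. No biological explanation was tested.

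The co-location of Spt16 with Oct4, Pou5f1 and Rif1 included, could arise from the libraries themselves. Oct4 reads mixed into the Spt16 library would leave Spt16 RPM at a minor share of Oct4 RPM, but the median ratio at shared regions was 1.14, and over all Oct4 regions it would be 0.870 even if each of the 97 unshared ones lay lower. Chance low input in the common control is argued against at 23 of the 168 shared regions, Abca4, Pou5f1 and Rif1 included, where the library totals allow under 0.05 chance calls of such a score genome-wide in each list. At another 71 that bound held in 1 list (for Spt16 at 93 of the 168 in all), which argues against low input as the cause of both calls but leaves the other call open, and at the remaining 74 it cannot be told apart, as neither score is high enough. Unspecific pull-down of open chromatin cannot be told apart from recruitment, since no control antibody and no 0 h Spt16 library was analysed here; 157 of the 168 shared regions were outside the Jmjd1c list, which held 24 regions, and recruitment of FACT by Oct4 also stays open, as untested.

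Among Jmjd1c regions, 7 of the 11 outside the Oct4 list held input reads, against 2 of the 13 inside it (Fisher's exact test, p = 0.033); those 7 included the regions near Zfp960, Gm10482 and Gm2389.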

How the results depend on the processing

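The overlaps of region lists kept direction and significance under each alternative run, but some sizes moved. The pluripotency calls for Oct4 and Spt16 kept theirs too, as did the overlaps of neighboring genes, which are not independent of the region overlaps. The Jmjd1c share on Spt16 regions fell from 58.3% to 22.7% (5) without the widest 5% of each list. Without regions in all 3 lists, by construction, it was 23.1% (3), and the share on Oct4 regions fell from 54.2% to 15.4% (2). In all, 136 comparisons of a result with an alternative kept direction and side of the threshold, or stayed within 1.5 times for counts; the exceptions follow, and where no construction shows the cause, the cause was not tested. The alternatives with thinned reads, other preset lists as background, ChIP reads alone, and without histone and U RNA genes were chosen after seeing the data. Regions at or above the median score numbered 135, 646 and 12 for Oct4, Spt16 and Jmjd1c, by construction, and thinning to the Oct4 depth left 594 Spt16 and 14.3 Jmjd1c regions. In that higher-scoring part, cell cycle genes by Spt16 (odds ratio 4.48, Fisher's exact test, adjusted p = 0.14) and the 1 kb difference between Oct4 and Spt16 (6.58 points, adjusted p = 0.0996) lost their calls, as did pluripotency by Jmjd1c (odds ratio 0, adjusted p = 1). Without regions at histone and U RNA genes, all of them Spt16 regions within 1 kb, the difference was 2.65 points, lower by construction. Against the other preset lists only, Spt16 calls ended for cell cycle (odds ratio 1.06), chromatin (0.979, reversed) and housekeeping genes (1.47), and calls of fewer genes appeared for retinoic acid response (0.147), for germ layer regulators (0.214, reversed) and for fibroblast or extraembryonic markers (0); there the comparison genes are themselves often marked. Pluripotency by Jmjd1c gave no finite odds ratio there (Fisher's exact test, adjusted p = 0.17), nor did the genes shared by Spt16 and Jmjd1c in the higher-scoring part (8 of 8, adjusted p = 5.51e-11). Results that had not passed the threshold changed direction without passing it in several alternatives. Against the other preset lists, Oct4 odds ratios were 0.813 for chromatin, 0.315 for germ layer, 0.494 for housekeeping and 0.341 for retinoic acid genes. Within 10 kb, they were 0 for chromatin, housekeeping and retinoic acid genes, while retinoic acid genes by Spt16 had 1.68, and 1.08 at any distance. The 10 kb difference between Oct4 and Jmjd1c was -26.5 points in the higher-scoring part, the Spt16 and Jmjd1c rho was -0.0071 without the 2 farthest regions, and Jmjd1c regions on Oct4 regions differed by -4 in ChIP reads. The Oct4 and Jmjd1c score correlation was rho 0.58 without the 2 farthest regions and 0.57 from ChIP reads alone (permutation adjusted p = 0.064; 0.012 to 0.098 over its alternatives), where r was 0.70 and passed (permutation adjusted p = 0.012). By ChIP reads alone, Jmjd1c regions in the Spt16 list had a median that differed from the others by -2.5 reads (permutation adjusted p = 0.65), where the score had been higher by 10.0. No paired analysis was possible because each antibody and time had 1 library. The octamer alternatives were not run, and distance from the region middle, named as an alternative, was the deposited one, so distance from the region edge was run in its place. Depth limits Oct4 most: its list starts at 15 reads, and weaker sites were not detectable.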

Other observations

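All tests in this part were chosen after the results were seen, as were the families and genes named.

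Some Spt16 regions outside the Oct4 list lay beside genes for histones and for small nuclear RNAs. Whether these genes had a Spt16 region more often than genes at large was not tested. Within 1 kb of replication-dependent histone genes lay 28 Spt16 regions, beside 36 deposited gene identifiers, the pseudogene Hist2h3c2-ps among them. The RefSeq table holds 68 protein-coding histone genes of this naming, a different set of genes, so these counts do not form a share. The histone regions included those at Hist1h1a (chromosome 13, 23855608 to 23856114; 45 reads against 0 input reads, at least 5.97-fold), Hist2h3c1 (41 against 0) and Hist1h2bg (36 against 0). Another 28 lay within 1 kb of U1, U2, U4, U5, U6, U7 or U11 genes, whose RNAs act in splicing or histone mRNA processing. They included U4 on chromosome 5 (115939614 to 115940313; 109 reads against 2), a U1 gene on chromosome 3 (88 against 2) and a U5 gene on chromosome 4 (75 against 0, at least 9.95-fold). No region of the Oct4 or Jmjd1c list lay within 1 kb of either family. The lists were not filtered alike: 10 regions found in uninduced cells were removed from the Oct4 list, and no such removal is noted for Spt16. Whether those regions, or the ones behind the 21 Oct4 and 28 Jmjd1c absent rank numbers, lay at these genes could not be checked.

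Smaller groups lay within 1 kb of Spt16 regions too. The Mir290 cluster, microRNAs typical of pluripotent cells, had 4 Spt16 regions on chromosome 7, the strongest at Mir290 (3217877 to 3219111; 63 reads against 0, at least 8.36-fold). Malat1, an abundant nuclear RNA, had 2 regions (39 and 34 reads against 0). Small nucleolar RNA genes had 13 and olfactory receptor genes 0. Each of the 7 families tested, of which 1 is not used here, was set alone against the Spt16 regions in the Oct4 list and did not pass the threshold (Fisher's exact test, adjusted p = 0.087 for histone and for U RNA genes, and 0.55 to 1 for the others). The histone and U RNA regions together made up 56 of the 1085 Spt16 regions outside the Oct4 list and 0 of the 168 inside it (Fisher's exact test, p = 0.00043, not corrected for the choice of families or for neighboring genes), but the 56 were weaker, with a median of 34 reads against 55 at the 168.

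The histone and U RNA regions lay on the transcribed side of the gene starts: 52 of the 56 were downstream (92.9%), with a median of 513 bp from the start for histone genes and 648 bp for U RNA genes, where 26 of 28 lay past the annotated gene end, as the genes have a median length of 163 bp. Of the histone regions, 9 of 28 lay past the gene end, and a region inside a gene counts as downstream. With neighbors counted once, as 16 or 14 clusters, 15 and 13 clusters lay mostly downstream and 0 mostly upstream (exact binomial p = 6.1e-05 and 0.00024). Reads of repeated gene copies placed on unique flanks cannot be told apart by side. They would fall on both sides only if unique sequence flanked the genes evenly, which was not examined here. Low input at these genes cannot be told apart as a contributor, since 80.4% of the 56 had no input read against 67.1% of the other Spt16 regions outside the Oct4 list (Fisher's exact test, p = 0.040), but by cluster the permutation p was 0.35 and 0.32. The larger Spt16 depth cannot be told apart as the reason for the 0 in the Oct4 list: at the rate of Spt16 regions of like score 6.64 of the 56 would be in it, and the probability of 0 was 4.03e-05 to 0.00028 with regions taken singly but 0.036 to 0.082 by cluster over the settings tried, and with Spt16 reads thinned to the Oct4 total, where 26.3 of the 56 passed and 5.87 would be in the Oct4 list at like thinned score, it was 0.00013 to 0.0014 singly and 0.0096 to 0.055 by cluster. At the other 92 gene starts with a Spt16 region outside the Oct4 list, 51.1% were downstream, so as a hypothesis Spt16 may follow transcription past the start at these short genes and be placed otherwise elsewhere (permutation test of the difference over clusters, p = 0.00012 and 0.0006), though whether these genes were transcribed in the cells was not measured here.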
